A study of Mus musculus with 8 samples.

How the data were processed

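Cells of erythroblastic islands were obtained from bone marrow and spleen on albumin gradients, set free by chelation and light mechanical force, and sequenced as 10x Genomics v3.1 libraries. The authors deposited 1 table of raw UMI counts per gene and cell, not normalised, with all libraries side by side. The submitters' processing notes name Cell Ranger 5.0.0, Seurat 3.1.5 and the mouse genome mm10. The filters the authors used on cells and genes are not given in the sources used here. The table held 19669 genes, of which 132 were at 0 in every cell, and 24942 cells with 500 to 83490 UMIs, 201 to 4999 genes and at most 20% mitochondrial UMIs.

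The labels give 8 libraries in 4 groups, but nothing in the table ties a cell to a library, so all cells were analysed as 1 pooled sample and none was assigned to a group. Barcode order restarted 7 times. The 8 sorted stretches were used as unnamed libraries, for ranges and for leaving out 1 at a time, a choice made after the data were seen. Their order was not used to infer a tissue or genotype. The tests planned between transgenic and control libraries and between spleen and marrow were not made, because no group could be formed.

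Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed none. Scrublet, applied within runs, called 17 doublets, 0.068% of the cells, and these were left out. Doublets that it did not call may remain. The remaining 24925 cells were scaled to 10000 UMIs and log-transformed in scanpy 1.11.5 under Python 3.11.15. The 2000 most variable genes, 30 principal components and 15 neighbours gave 39 Leiden clusters at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0, seed 0). The runs entered only the choice of variable genes, and no correction for differences between them was made before clustering. The genes of a cluster with at least 50 CPM were ranked by their ratio to all other cells, with 10 CPM added to both. A cluster was named for the class, of 15 with marker lists, that had most markers among its 50 leading genes, if at least 3 of that class's markers reached 50 CPM. It stayed unnamed where another class had as many markers among the 10 leading genes, or where depth was low and none of the 10 was a marker of the class. Names end in -like because they rest on RNA alone.

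UMIs were summed per class and scaled to CPM (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with exact 95% Poisson intervals for levels and exact Clopper-Pearson binomial intervals for shares of cells. For a class at 0, the level of 3 UMIs was taken as the upper limit. Between classes, the log2 ratio was taken after adding 10 CPM to both levels, for genes of at least 20 CPM in either class, and centred on the median gene. The centring was chosen after globin was seen to fill the late erythroid-like cells. On this centred scale, a member of a list was counted as higher or lower when it was at least 2-fold apart in the pooled cells. It also had to have the same sign in every run with at least 20 cells of both classes. These counts describe the pooled cells and are no test. Each list was ranked among 10000 random lists matched in level over 20 bins, and had an interval from 2000 bootstrap draws of its members.

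The 22 gene lists, the marker lists, the filters and the cluster settings were fixed before the data were examined. So was the rule for genes to name, written for comparisons between groups. It took the 10 highest and 10 lowest past the threshold, up to 4 members of each list, the Toll-like receptors Tlr7, Tlr8 and Tlr9, and a short set of island, red cell and myeloid genes. Predicted genes, antigen receptor segments and mitochondrial genes were not named. Here the rule was applied to the differences between classes by size, with the 2-fold rule in place of a test. Other genes the text names, among them Tlr13, Unc93b1 and most of those in the other observations, were chosen after their values were seen. Gene positions are from GENCODE release M21 for GRCm38.

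The calculation was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. Each was raised or lowered at random. The direction was right in 100% of them, and the intervals held the true ratio in 94 to 98%. The added 10 CPM drew the recovered log2 differences in, to between 0.836 and 0.866 of a true 1. No unchanged gene reached 2-fold. These results check the calculation for counting error alone. They do not test the clustering, the spread between runs or the centring where globin filled the late erythroid-like cells.

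Alternatives changed 1 choice at a time, except that those on the cell filter changed 2 criteria together. They covered cluster resolutions 0.5 and 2, no filter and doublets kept, a filter of 500 genes and 10% mitochondrial UMIs, globins left out and markers left out. Added after the data were seen were plain totals, a pseudocount of 1, repeated barcodes left out, clustering without the listed genes, the highest 6% of doublet scores left out, high-globin cells left out and each run left out.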

Results

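The series holds single-cell RNA sequencing of erythroblastic island cells, the clusters of red cell precursors around a central macrophage, from male mice of the lupus-prone Sle1.Yaa strain. Some mice carried a human TLR8 transgene and were labelled anemic, and their controls were labelled non-anemic. Per the labels there were 2 transgenic and 3 control marrow libraries, with 2 transgenic spleens and 1 control spleen. The deposited table held 24942 cells and 19669 genes with 248384567 UMIs, but its columns carried cell barcodes alone, with no library or group. The effect of the transgene and the difference between spleen and marrow could therefore not be measured, and no planned test between groups was made. What could be described was which cells the island preparations held and how their classes differed, with the libraries pooled. Nothing in the table shows whether a given cell had been part of an island.

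The barcodes fell into 8 alphabetically sorted runs, as many as the libraries, and each run was treated as 1 unnamed library. The runs held 447 to 6787 cells and 6195876 to 48442321 UMIs. Cells had a median of 7554 UMIs and 1584 genes. Levels are in CPM, the UMIs of a gene scaled by all UMIs of its class. All values are pooled over runs. The main shares and receptor levels have 95% exact binomial or Poisson intervals, which cover counting error alone, and the main list medians have the lowest and highest run. Single genes compared between classes are given as pooled levels, which also carry the uneven shares of the runs in each class, and except for Tlr7 and Tlr8 each one named kept its sign relative to the median gene in every run compared. A member of a list is counted as higher or lower when it was at least 2-fold apart relative to the median gene in the pooled cells. It also had to have the same sign in every run compared. No run could be called a replicate of any group, so no test between groups was made. The classes were described and not tested against each other within runs. The 4 comparisons of classes were chosen after the data were seen.

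Red cell precursors made up 40.9% of the 24925 cells that were clustered (95% interval 40.3 to 41.5), with 15.2 to 78.6% in single runs. Late erythroid-like cells, in which globin took 63.2% of UMIs, held 29.5% of cells, and early erythroid-like cells held 11.3%. Early cells were 27.7% of the erythroid total (26.9 to 28.6), and 18.1 to 56.3% in single runs. Neutrophil-like cells were 16.9% of all cells (16.4 to 17.4), from 1.14% of a run to 39.0%. Macrophage-like cells, the class that should hold the central cell of the island, were 2.96% (2.76 to 3.18) and 0.613 to 15.4% in single runs. This share joins unlike clusters, 476 cells led by Cd5l, Hmox1 and Vcam1 and 263 cells led by Fcgr4 and Cd300e. Dendritic cell-like cells held 5.91% and B cell-like cells 4.71%. Granulocyte-monocyte progenitor-like cells held 3.74%, T and NK cell-like cells 3.69% and monocyte-like cells 3.37%. Plasma cell-like cells, which secrete antibody, were 1.62% overall and 16.4% of 1 run. The 4 clusters left unnamed held 10.5% of the cells, and in 3 of them another class had as many markers among the leading genes. The largest of these, 1263 cells with a median of 813 UMIs, was led by Fcgr4, C1qb and Cd300e, as was a macrophage-like cluster, and is not in the macrophage-like share. The macrophage-like share was 8.50% with coarser clusters and 5.48% when cells under 500 genes or over 10% mitochondrial UMIs were left out.

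**Figure D1:**
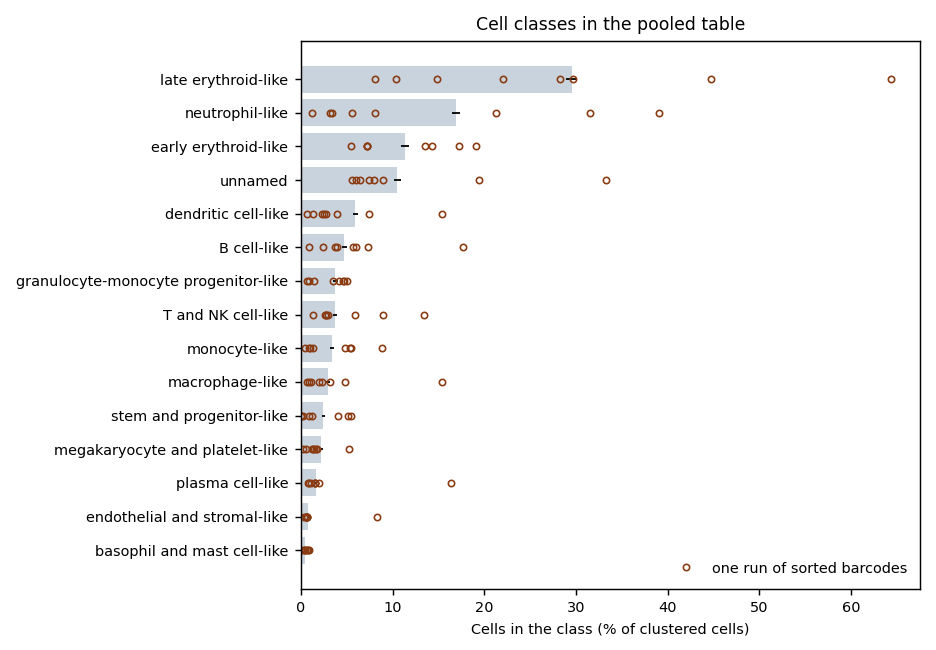
Share of the clustered cells in each class, in percent, with bars for all 8 runs pooled, lines for exact 95% binomial intervals and open circles for single runs. Late erythroid-like cells hold 29.5% of the pooled cells and 8.02 to 64.4% of single runs, so the circles spread far beyond the counting intervals.

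Toll-like receptor genes for RNA were read mainly in myeloid and dendritic classes and hardly in red cell precursors. Tlr7, a sensor of single-stranded RNA (GRCm38 chromosome X, 167304929 to 167330558, minus strand), stood at 80.7 CPM in dendritic cell-like cells (75.3 to 86.4). It stood at 73.7 in macrophage-like cells (66.3 to 81.7), 43.6 in monocyte-like cells and 22.7 in B cell-like cells. The macrophage-like level mixed 106.5 CPM in 1 cluster, led by Cd5l, with 44.4 in the other, led by Fcgr4. With coarser clusters the direction of this Tlr7 difference turned. The dendritic cell-like class was a mix too. It joined clusters of 746 and 206 cells, both with Siglech and Ccr9 among their leading genes, with 520 cells led by Tbc1d4 and Dntt. Of the 746 cells 99.06% came from 1 run, and Tlr7 was not taken for these clusters apart. Late erythroid-like cells held 12 Tlr7 UMIs, or 0.18 CPM. Mouse Tlr8, its neighbour (chromosome X, 167242696 to 167264329, minus strand), stood at 28.7 CPM in macrophage-like cells (24.2 to 33.8, single runs 20.02 to 43.9). Monocyte-like cells held 13.4 CPM of Tlr8 (11.5 to 15.5), and in the 4 runs with enough of both the log2 difference of Tlr8 between these classes ran from -0.05 to 1.90, with 3 runs above 0. Dendritic cell-like cells held 0.49 CPM of Tlr8 from 5 UMIs, and early erythroid-like and B cell-like cells 0 UMIs. In early erythroid-like cells the count of 0 allowed a Tlr8 level of up to 0.0812 CPM, that of 3 UMIs. Tlr13, a sensor of bacterial ribosomal RNA (chromosome X, 106143204 to 106160493, plus strand), was read at 39.6 CPM in monocyte-like cells, 24.2 in macrophage-like cells and 18.8 in neutrophil-like cells. Tlr9, the DNA sensor (chromosome 9, 106222598 to 106226883, plus strand), was near the detection limit, with 2.54 CPM from 16 UMIs in B cell-like cells. Unc93b1, the chaperone that carries these receptors to the endosome, stood at 541 CPM in macrophage-like cells (521 to 562), 393 in dendritic cell-like cells and 1.77 in late erythroid-like cells. The human TLR8 transgene was not analysed here.

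**Figure D2:**
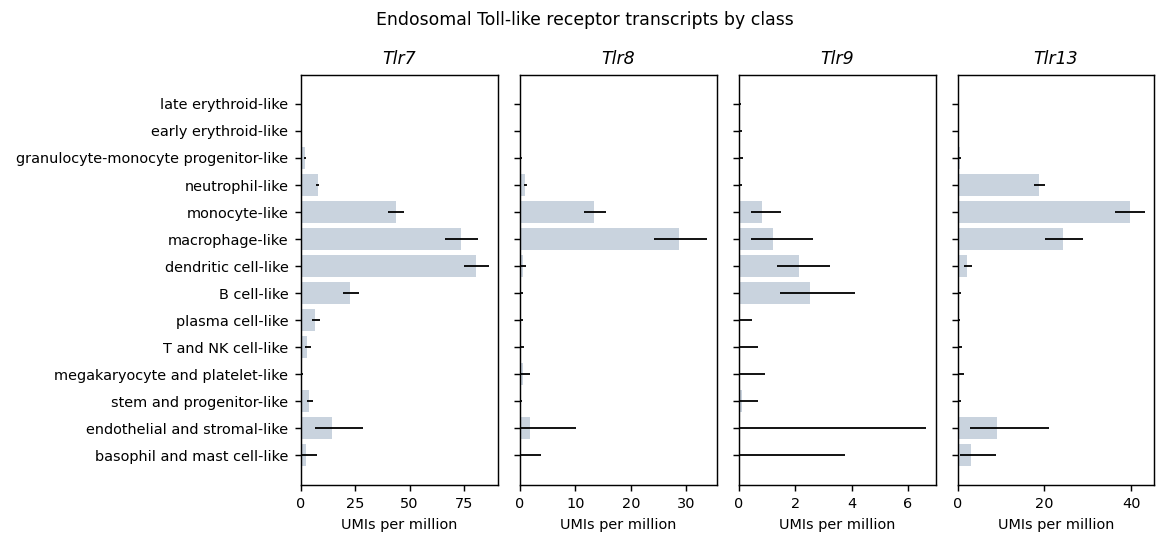
CPM of Tlr7, Tlr8, Tlr9 and Tlr13 in each of 14 cell classes, with bars for all runs pooled and lines for exact 95% Poisson intervals. Tlr7 reaches 80.7 in dendritic cell-like and 73.7 in macrophage-like cells, pooled Tlr8 is at 28.7 in macrophage-like and 13.4 in monocyte-like cells, and pooled Tlr13 at 39.6 in monocyte-like cells.

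Late erythroid-like cells were compared with early ones to describe red cell maturation in the island preparations. Log2 differences between classes are given relative to the median measured gene, because globin filled so much of the late cells that this median stood at -1.19 on plain totals. The 2-fold rule used this scale too. A gene at like CPM in both classes could thus count as higher. One such gene was Kif23, of the mitosis list, at 105 CPM in late and 115 in early cells. Terminal maturation genes had a median log2 difference of 2.49 (1.35 to 2.52 across the 8 runs), and 16 of 17 were higher by the 2-fold rule. Bpgm, which makes the regulator of oxygen release, stood at 856 CPM in late and 34.8 in early cells, and Bcl2l1, which protects late precursors from apoptosis, at 186 and 16.7. Genes of the red cell membrane and its skeleton followed at 1.43, with 17 of 19 higher by the rule. Epb41, the skeleton protein 4.1, stood at 643 and 159 CPM, and Slc4a1, the anion exchanger band 3, at 2534 and 1334. Heme synthesis genes had a median of 1.0 relative to the median gene but -0.19 on plain totals. Alas2, the rate-limiting enzyme of erythroid heme synthesis, stood at 1653 and 379 CPM and was higher on both scales.

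Measured genes of the type I interferon response were also higher in the late cells, by a median of 1.56 (0.95 to 1.75 across runs). Of these 16 genes, 14 were higher by the rule. The data held 37 genes of this list, and the others stayed below the minimum level of the comparison in both classes. The median thus describes the measured members and not the whole list. Lists foreign to red cells stood higher as well, by 1.44 for neutrophil granules, with 6 of 7 higher by the rule, and by 0.95 for immunoglobulin and plasma cell genes, against 1.56 for interferon and 1.43 for membrane genes. On plain totals these medians were 0.26, -0.23, 0.37 and 0.25. Among 10000 random lists matched in level, the interferon median was above 100%, that of neutrophil granules above 99.86% and that of immunoglobulin genes above 99.08%. Rsad2, the antiviral enzyme viperin, stood at 602 CPM in late and 40.8 in early cells, and Isg15, a ubiquitin-like modifier, at 993 and 130. Oasl2, an antiviral oligoadenylate synthetase-like protein, stood at 38.4 and 8.61. Rsad2, Isg15, Bpgm, Bcl2l1, Slc4a1 and Alas2 were among the genes that led single late clusters, and Mcm3 led an early one, so their levels helped to define the classes. With all genes of the fixed lists kept out of the clustering, the interferon median was 1.45.

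DNA replication genes stood lower in late cells, with a median of -0.86 (-1.16 to -0.53 across runs) and 6 of 25 lower by the rule. Mcm3, part of the replicative helicase, stood at 59.4 CPM against 442, and Dut, which keeps uracil out of DNA, at 53.8 against 564. Glycolysis and hypoxia genes had a median of -0.91, and 4 of 12 were lower by the rule. Ldha, which makes lactate, stood at 12.2 against 221 CPM, and Gapdh at 96.1 against 938. Mitosis genes had a median of 0.68 relative to the median gene and -0.51 on plain totals, with 5 of 25 higher by the rule. With globins left out of the totals their median was 0.96, with 12 of 25 higher. Outside the lists, Npm1, a nucleolar protein of ribosome assembly, stood at 59.95 CPM against 1288, and Ybx1, which binds messenger RNA, at 35.4 against 700.1. S100a8, a neutrophil granule gene, was read at 377 CPM in late and 271 in early cells.

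Macrophage-like cells were compared with monocyte-like cells to describe how the classes of the mononuclear phagocytes differed. The run with most macrophage-like cells, 268 of 739, held under 20 monocyte-like cells. It is in the pooled levels but not among the 4 runs compared. The classes came largely from unlike runs. Monocyte-like cells were 8.80% of a run with 0.83% macrophage-like cells, and 0.98% of the run with 15.4%. Among the 4 runs compared, monocyte-like cells went from 0.40% of a run with 2.32% macrophage-like cells to 5.43% of a run with 1.91%. Pooled differences between these classes thus also hold differences between runs. The macrophage-like class joined 2 unlike clusters, and its pooled levels mix them, as for Vcam1 with 4395 CPM in its Cd5l-high and 52.03 in its Fcgr4-high cluster. Genes of adhesion and of the uptake of dying cells had a median log2 difference of 2.19 (1.37 to 3.21 across 4 runs), with 14 of 19 higher by the rule and 1 lower. Iron and heme recycling genes stood at 1.67 (0.83 to 1.77), with 9 of 20 higher. Cp, a ferroxidase that loads iron onto transferrin, was read at 149 CPM in macrophage-like and 2.13 in monocyte-like cells, with a log2 difference from 0.19 to 3.67 in single runs. Hmox1, Slc40a1, Spic, Vcam1 and C1qa were higher too, but they are macrophage markers used to name the class. Without such markers the medians were 1.04 for adhesion and 0.96 for recycling, and over the members that were not among the variable genes used for clustering they were 0.64 and 0.81.

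Outside the markers, Igf1, a growth factor, stood at 262 CPM in macrophage-like and 0.46 in monocyte-like cells. Itgad, the alpha D integrin of red pulp macrophages, stood at 275 and 0.53, Gdf15, a stress cytokine, at 340 and 9.37, and Lgmn, a lysosomal protease, at 972 and 56.4. Within the class, Gdf15 stood at 666 CPM in Cd5l-high and 48.97 in Fcgr4-high cells, and Lgmn at 1745 and 281. Glycolysis and hypoxia genes were lower in macrophage-like cells by a median of -0.86 (-0.80 to -0.58 in the 4 runs compared), with 7 of 18 lower by the rule and 2 higher. Their Eno1, a glycolytic enzyme, stood at 130 against 549 CPM. Plac8 and Hp, genes of bone marrow myeloid cells, stood at 26.5 against 2447 and at 14.1 against 1488. Type I interferon genes differed less, with a median of 0.54 and runs from -0.23 to 0.76, and 7 of 33 were higher and 3 lower. Over the 16 of them not used for clustering the median was -0.12. The 4 measured globins were all higher, by a median of 4.38 over all runs and 1.13 to 3.04 in the 4 runs compared. Of the 739 macrophage-like cells, 57 carried over 10 times the globin UMIs of other classes in their run, and 40 of these came from 1 run.

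Macrophage-like cells fell into a cluster of 476 cells led by Cd5l, Hmox1 and Vcam1 and another of 263 cells led by Fcgr4 and Cd300e. All 6 measured MHC class II genes, which present antigen, were higher in the Cd5l-high cells by the rule, over the 2 runs compared, with a median log2 difference of 1.84 (1.38 to 2.18). Of these 6 genes 4 are class markers and all took part in the clustering, and with the listed genes kept out of it the median was 2.44. Cd74, the invariant chain, stood at 3170 CPM in Cd5l-high and 653 in Fcgr4-high cells. Genes of patrolling monocytes had a median of -1.59 (-1.39 to -0.83), with 8 of 14 lower by the rule and 2 higher. Itgax, the integrin CD11c, stood at 26.5 against 420 CPM, Spn, the sialophorin CD43, at 12.8 against 235, and Cx3cr1, the fractalkine receptor, at 17.96 against 201. Trf, transferrin, stood at 1021 against 11.1 and Mertk, a receptor for dying cells, at 376 against 13.01.

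Cytokine genes went both ways between these macrophage-like clusters. Igf1 stood at 548 CPM in Cd5l-high and 5.36 in Fcgr4-high cells, and Il18 at 237 and 6.50. Il1a was read with 127 UMIs against 0. Il1b stood at 100.1 against 787 and the chemokine Ccl3 at 252 against 1541, both lower in the Cd5l-high cells. Of 25 inflammatory genes 5 were higher and 5 lower by the rule, and of 33 type I interferon genes 4 were higher and 4 lower. Genes induced by dissociation of tissue had a median of -0.48 (-0.98 to -0.50 in the 2 runs compared), with 3 of 20 lower by the rule and 1 higher. Membrane and skeleton genes of the red cell stood 1.42 higher in the Cd5l-high cells, with 13 of 14 higher by the rule, and at 0.78 without the cells far above their run's globin level. The Cd5l-high cells were shallower, with a median of 2144.5 UMIs against 8047. With coarser clusters the MHC class II median was 0.79, and Tlr7 turned from 1.12 to -0.93.

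Neutrophil-like cells were compared with granulocyte-monocyte progenitor-like cells to describe granulocyte maturation. Neutrophil granule genes had a median log2 difference of 2.84 (1.94 to 3.47 across 7 runs), with 15 of 20 higher by the rule and 4 lower. Most of these are markers of the classes. Inflammatory cytokines and NF-kB targets stood 1.94 higher (1.24 to 2.23), with 12 of 17 higher and 1 lower. Nfkbiz, an inducible NF-kB regulator, was read at 433 CPM in neutrophil-like and 39.7 in progenitor-like cells. Type I interferon genes stood 1.27 higher (0.46 to 2.06 across runs), with 10 of 13 higher and 1 lower, and at 0.84 on plain totals. Ifitm3, which blocks viral entry, stood at 958 and 111 CPM. Genes induced by dissociation of tissue stood 1.09 higher as well, with 9 of 19 higher and 4 lower.

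Unfolded protein and integrated stress response genes stood lower in neutrophil-like cells, at -1.04 (-1.29 to -0.91 across runs), with 7 of 14 lower by the rule and 1 higher. The list was mixed, with a bootstrap interval of -1.996 to 0.22 and a median of 0.22 over the 8 members not among the variable genes, while with all listed genes kept out of the clustering it stood at -1.01. Sdf2l1, an endoplasmic reticulum chaperone partner, was read at 15.7 CPM against 306, and Pdia6, a disulfide isomerase, at 35.7 against 436. DNA replication genes stood at -0.63, with 5 of 24 lower by the rule, and mitosis genes at 0.47, or 0.04 on plain totals, with 2 of 24 higher. Lgals3, a lectin, stood at 599 in neutrophil-like against 35.7 in progenitor-like cells, and Fpr2, a receptor for formylated peptides, at 152 against 1.06. Mif, a cytokine, stood at 25.7 against 423 and Srm, an enzyme of polyamine synthesis, at 2.53 against 116.

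**Figure D3:**
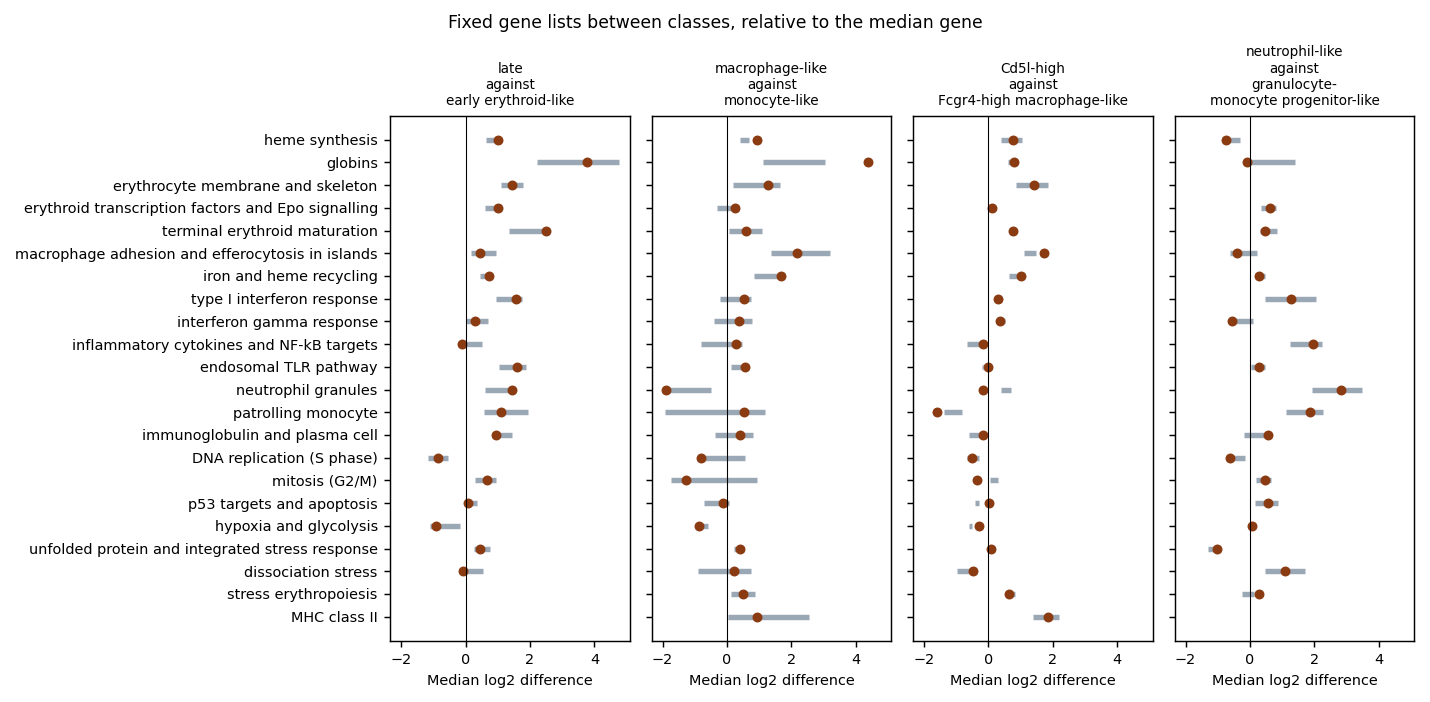
Median log2 difference of the members of 22 gene lists in 4 comparisons of classes, relative to the median measured gene, where at least 3 members were measured, with dots for pooled values and grey lines from the lowest to the highest run compared. On plain totals every dot of late against early erythroid-like cells stands -1.19 from where it is drawn, so heme synthesis goes from 1.0 to -0.19 and mitosis from 0.68 to -0.51, and every dot of neutrophil-like against progenitor-like cells stands -0.43 from it.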

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

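Plain totals, the pseudocount of 1, the clustering without listed genes, and leaving out runs, repeated barcodes, high-globin cells or high doublet scores were alternatives chosen only after the results were seen, unlike the separate tests on barcodes and runs. Of the values for the 11 main list medians under all alternatives, 208 stayed within their bootstrap interval, 10 moved beyond it with the same sign and 1 reversed. Of 11 further list medians taken through the alternatives 201 stayed, 18 moved and 1 reversed. For the 4 main shares of cells 25 values stayed within the binomial interval and 39 moved, and for the other shares 73 stayed and 71 moved. The binomial interval covers counting alone. Other clusterings can place cells in other classes, and leaving out a run changes which cells are counted. Where no reason is given, the cause was not tested.

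On plain totals, late against early erythroid-like cells gave medians of 1.31 for terminal maturation, 0.37 for type I interferon and -2.04 for DNA replication. Heme synthesis reversed to -0.19 and mitosis to -0.51, since this scale moves every gene of that comparison by -1.19. Of the lists not taken through all alternatives it also turned 8, to between -1.10 and -0.08, among them iron recycling at -0.46, erythroid transcription factors at -0.18 and interferon gamma at -0.89. In neutrophil-like against progenitor-like cells it turned 4 lists, to between -0.36 and -0.14. With class markers left out, adhesion genes in macrophage-like against monocyte-like cells were at 1.04, by construction with fewer genes.

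At Leiden resolution 0.5 neutrophil-like cells were 14.9% of cells, macrophage-like cells 8.50% and early cells 23.6% of the erythroid total, and the adhesion median was 1.68. At Leiden resolution 2 these shares were 14.9%, 3.25% and 32.3%. With at least 500 genes and at most 10% mitochondrial UMIs, erythroid-like cells were 38.01%, neutrophil-like cells 18.01%, macrophage-like cells 5.48% and the early share 35.3%. With repeated barcodes left out, erythroid-like cells were 42.4%, neutrophil-like cells 14.5% and macrophage-like cells 3.60%. Clustered without the listed genes, neutrophil-like cells were 16.3% and the early share was 31.3%. Without high-globin cells macrophage-like cells were 2.75%. The MHC class II median of Cd5l-high against Fcgr4-high cells was 0.79 at resolution 0.5, 2.61 at resolution 2, 2.71 with the stricter filter, 2.39 without repeated barcodes and 2.44 without listed genes in the clustering.

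Leaving out each run in turn gave 35.9 to 43.6% for erythroid-like cells, 12.3 to 20.2% for neutrophil-like cells, 2.03 to 3.34% for macrophage-like cells and 25.2 to 30.5% for the early share.

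Named genes at least 2-fold apart relative to the median gene mostly kept their sign under every alternative. They were 70 of 77, 75 of 78, 70 of 77 and 64 of 64, in the order of the comparisons in the report. No test of the classes paired by run was made. Pairing by mouse was not possible, because no cell could be tied to a mouse. Other settings planned for tests between groups were not run for the same reason. These were another tool and other size factors, no filter on low counts, leaving out replicates, marrow or transgenic libraries alone, self-contained and correlation-adjusted list tests, and free RNA markers left out of tests. Depth limits Tlr9, with 16 UMIs in its highest class, and genes of classes with few cells.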

Other observations

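The barcode tests and the test of a shift between runs were set before their results were seen, and the 5 globin tests were chosen only after the result was seen, as were most genes named in this part. Interferon-stimulated genes did not share 1 distribution over the classes. Isg15 stood at 993 CPM in late erythroid-like cells (473 to 1498 in single runs) and 475 in macrophage-like cells, and Rsad2 at 602 and 299. Ifit3, from the same response, was read with 13 UMIs in late erythroid-like cells, or 0.19 CPM, and with 603 UMIs, or 122 CPM, in macrophage-like cells. Ifit1 stood at 24.1 and 113. Ifng, the type II interferon, was read in T and NK cell-like cells at 346 CPM (330 to 362, single runs 51.6 to 616). Cxcl9 and Cxcl10, chemokines that interferon gamma induces, stood at 429 and 310 CPM in endothelial and stromal-like cells. Cxcl10 stood at 265 in T and NK cell-like cells and 118 and Cxcl9 at 52.7 in macrophage-like cells.

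Kitl, the ligand of the Kit receptor, stood at 346 CPM in the 176 endothelial and stromal-like cells (299 to 398) and at 21.2 in macrophage-like cells. Gas6, a bridge between dying cells and their receptors, stood at 342 and Bmp4, a signal of stress erythropoiesis, at 32.4 in endothelial and stromal-like cells. Il6 stood at 444 CPM in the 112 basophil and mast cell-like cells (404 to 488) and at 17.8 in macrophage-like cells. Tnfsf13b, the B cell survival factor BAFF, stood at 39.6 in neutrophil-like cells (37.9 to 41.3) and 7.88 in macrophage-like cells. Erfe, by which red cell precursors lower hepcidin, was read at 30.6 in early and 18.3 in late erythroid-like cells. These levels are plain CPM, on which the median measured gene stood at -1.19 in late against early cells. Relative to that gene Erfe was not lower in the late cells. A cluster of 116 monocyte-like cells with high Ace held Tlr7 at 170 CPM (137 to 208).

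Globin RNA stood far above the level of other classes in 57 of the 739 macrophage-like cells (7.71%, 5.89 to 9.88), which held 84.3% of the globin of the class, and 40 of the 57 came from 1 run. Such cells occurred elsewhere too, as in 4 of 176 endothelial and stromal-like and 13 of 541 megakaryocyte and platelet-like cells. Globin took 4.34% of UMIs in endothelial and stromal-like cells against 2.91% in macrophage-like cells. At the joint rate of the other classes in each run there would have been 5.73 such cells (upper limit 12.7). Pooled over runs, that rate was itself uneven, from 0.12% in monocyte-like to 2.40% in megakaryocyte and platelet-like cells. The share in macrophage-like cells was above that of each other class. Because the rate differed between classes, the test cannot exclude red cell precursors caught in the same droplet by chance. The number argues against free RNA alone as the source in these 57, on the premise that free RNA gives all classes of a run a like level. Free RNA alone may account for the globin of the other macrophage-like cells, whose median per cell was over 1.5 times that of other classes in 0 of 5 runs (0.479 to 1.01 times), although the globin share of the whole class was over 1.5 times in 3 of 5. Precursors attached to or inside the macrophage could be the source in the 57 cells, whose median doublet score was 0.068 against 0.04 in the rest, but no test decided it. Late erythroid genes other than globins stood at 2.06 times their ratio to globin in late erythroid-like cells, or 1.03 times without Acp5, which macrophages express, but this was taken over all 739 cells and any RNA of late erythroid cells would give a ratio near 1.

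In all, 287 barcodes occurred in several runs, in 1031 cells with a median of 851 UMIs against 7554 over all cells. Chance reuse was excluded, with 157 barcodes in 3 or more runs against 0.368 from chance (upper limit 4.42). Reads of 1 cell assigned to other libraries sequenced with it may be the source. Copies of a barcode were more alike than random cells by a correlation of 0.0707, between the bounds of 0.05 and 0.2, so the test left it open. Of these cells 46.1% were in unnamed clusters, and no biological explanation was tested.

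Runs differed from one another within a class, and a shift of the whole library was weighed as a technical source. The differences of a run correlated between unlike classes with a median r of 0.293 across genes (0.205 to 0.380 over the runs), between the bounds of 0.2 and 0.5. The test left the shift open, and it may account for part of the differences. Some clusters came almost wholly from 1 run, that of 6787 cells. It held 99.06% of a dendritic cell-like cluster of 746 cells and 98.85% of a progenitor-like cluster of 261. Of a late erythroid-like cluster of 1344 cells it held 94.94%, and of an early one of 444 cells 94.59%. The clusters are thus not all shared over the runs, and the reason was not tested. Genes are not independent replicates. Genotype and tissue, which the labels give for libraries but not for cells, stay open and untested.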
